A study of Homo sapiens with 12 samples.

How the data were processed

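Total RNA of 12 samples was hybridised, per the labels, to Affymetrix arrays after biotin labelling: 3 arrays each of abl siCtrl, abl siEZH2, LNCaP siCtrl and LNCaP siEZH2. The values used are log2 expression values, 1 per probe set and array, made by the authors with RMA, per the submitters' processing notes, and taken from the deposited value table of the series. The RMA settings, and which arrays were normalized together, are not given in the sources used here. The log2 scale was read from the values. The 12 columns do not share 1 distribution. Array medians ran from 6.11 to 6.51 and interquartile ranges from 2.52 to 2.99, so differences between lines carry an unknown scaling.

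Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. No 2 arrays were duplicates: the closest, LNCaP siCtrl replicates 1 and 2, correlated with r = 0.996, and at most 122 probe sets had identical values in any 2 arrays. Within a line every 2 arrays shared at least 35 identical values, while no abl array shared any with an LNCaP array. The lines may therefore have been processed apart, which was not tested. Another 12 columns of per-sample values, in 2 gene-level tables, were not used because their headings match no sample's labels. Those tables hold the gene names, and no table used here pairs the probe sets with genes. The plan had been to test 1 probe set per gene and 19 gene lists fixed in advance. In its place all probe sets were tested singly, no list was tested, and no probe set was named as EZH2. Of the probe sets, 62 with identifiers that begin with AFFX are array controls and were left out of the fits, which left 54613. Dim probe sets were kept.

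The tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, Benjamini-Hochberg adjustment over all probe sets, threshold 0.05). The fit fixed before the data were examined had the 4 group means and all 12 arrays, with 8 residual degrees of freedom. An alternative fixed at the same time added the replicate number within each line as a block, with 4 residual degrees of freedom. For the control lines it used the siCtrl arrays alone with the number as a block over both lines, with 2 residual degrees of freedom. The numbers were taken to pair the arrays because same-numbered arrays deviated together from their group means: over probe sets, r was 0.860, 0.771 and 0.678 in abl, 0.848, 0.658 and 0.736 in LNCaP, and 0.752, 0.643 and 0.560 between the control groups. The criterion, every r over 0.1, was set beforehand. Arrays of replicates 1 and 2 met it across numbers too, with r of 0.491 and 0.618 in abl and 0.738 and 0.6625 in LNCaP. Between the control groups such r were 0.626 and 0.535. With replicate 0 far apart, the criterion could hardly fail, so it does not show that the numbers pair replicates 1 and 2. The calls of both fits were seen together with this check, and the pairing rests on the data, not on a stated batch. In LNCaP, replicate 1 of both siRNAs and siEZH2 replicate 2 deviated most like an array of another number, while every abl array deviated most like the other array of its own number. The block lowered the median residual SD from 0.252 to 0.134 on the log2 scale.

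The probe sets named for each comparison follow a rule fixed before the data were examined. It takes the largest changes past the threshold among probe sets above the median level whose groups do not overlap, or, where none passed, those with the smallest unadjusted p in the unpaired fit. At most 2 per direction are given because they carry no gene name. Exceptions chosen after seeing values are named as such. Array properties were compared between replicate 0 and the other arrays with exact permutation tests, and between siRNAs within pairs with exact sign-flip permutation tests, both two-sided. The test within pairs was chosen after seeing the data. Lists of calls were set in the other line against 10000 random lists drawn from 20 bins of mean level.

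The fits were tested on simulated data with the real block effects and residual SDs and 200 probe sets changed in each comparison, among 54613. Noise was drawn independently for each probe set and array, and for the siEZH2 comparisons the simulated model is that of the paired fit. Shifts shared across probe sets are left out, so the false calls are no error rate for the real arrays. For abl, the paired fit recovered 32.8% of 1.5-fold, 70.1% of 2-fold and 98.5% of 3-fold changes with 5 false calls, and the unpaired fit 0%, 10.4% and 75.8% with 0. For LNCaP, the paired fit recovered 32.8%, 73.1% and 95.5% with 2 false calls, and the unpaired fit 0%, 14.9% and 45.5% with 0. For the control lines, the paired fit recovered 0%, 0% and 80.3% with 1 false call, and the unpaired fit 0%, 25.4% and 62.1% with 0.

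Alternatives were another scaling (median centring, quantile normalization), a filter to probe sets above the median level, leaving out the 15499 probe sets with identifiers ending in _x_at or _s_at, variance moderation with a trend, only the arrays compared, and leaving out arrays in turn. Leaving out all replicate 0 arrays, a batch term for replicate 0, and the alternatives run on top of the block were added after seeing the data.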

Results

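Total RNA was profiled on Affymetrix expression arrays from LNCaP, an androgen-dependent human prostate cancer cell line, and from LNCaP-abl (abl), a line derived from LNCaP that grows without androgen. Cells of each line received a control small interfering RNA (siCtrl) or small interfering RNAs against EZH2 (siEZH2), the histone methyltransferase of Polycomb repressive complex 2. LNCaP cells were kept routinely in medium with fetal bovine serum and abl cells in medium without phenol red and with the serum charcoal-stripped. For the experiment, after 24 h in androgen-depleted medium, LNCaP cells were given 10 nM dihydrotestosterone and abl cells ethanol vehicle for another 24 h. The 4 groups held 3 arrays each, 12 in all, and the number of arrays limits the precision of every value. The comparisons ask which transcripts depend on EZH2 in each line, whether the 2 lines differ in this, and how the control cells of the lines differ. The value table names its probe sets by identifier and pairs none with a gene. No probe set is therefore given a gene name here, the silencing of EZH2 was not checked against a named probe set, and the gene lists fixed in advance were not tested. Neither annotation nor coordinates of the probe sets were used here.

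The arrays separated by cell line and by replicate number before they separated by siRNA. The first principal component of the 54613 probe sets tested held 51.6% of the variance and placed all 6 abl arrays apart from all 6 LNCaP arrays. The second held 34.2% and placed the 4 replicate 0 arrays, one of each group, between 66.5 and 95.7, while the other 8 arrays lay between -64.5 and -12.4. Replicate 0 arrays had a narrower spread of log2 values, with an interquartile range of 2.54 ± 0.0166 (SD, n = 4) against 2.93 ± 0.0561 (SD, n = 8) in replicates 1 and 2 (exact permutation test, two-sided, p = 0.00202, adjusted p = 0.00242 over the 6 array properties tested). Their 3' to 5' gap, the log2 value of the 3' control probe set minus that of the 5' one, was 0.821 ± 0.109 (SD, n = 4) against 0.387 ± 0.0616 (SD, n = 8) for the control probe sets with HSAC07 in their identifier (exact permutation p = 0.00202, adjusted p = 0.00242). It was 0.372 ± 0.0898 (SD, n = 4) against 0.0267 ± 0.0485 (SD, n = 8) for those with HUMGAPDH in theirs (exact permutation p = 0.00202, adjusted p = 0.00242). Within pairs of the same line and replicate number, several properties also moved with the siRNA. In all 6 pairs the siEZH2 array had the narrower interquartile range, by a mean of -0.057 ± 0.0479 (SD, n = 6 pairs), and the higher score on the second component, by 11.1 ± 6.37 (SD, n = 6), which is toward replicate 0. The control probe set AFFX-HUMRGE/M10098_3_at was higher in siEZH2 in all 6 pairs, by 0.61 ± 0.515 (SD, n = 6), and so was AFFX-M27830_3_at, by 0.10 ± 0.0312 (SD, n = 6). Each of these had an exact sign-flip permutation p of 0.0312, two-sided, the smallest that 6 pairs can give, and an adjusted p of 0.0669 over the 15 properties tested. The HSAC07 gap was wider in siEZH2 in 3 of 3 abl pairs, by 0.229, 0.0129 and 0.0045, and in 1 of 3 LNCaP pairs (exact permutation p = 0.344 over both lines, adjusted p = 0.369). By mean, 3496 probe sets were 1 log2 unit or more lower in replicate 0 than in the other arrays, and 446 were higher by as much. A shift toward replicate 0 could therefore give more falls than rises.

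**Figure D1:**
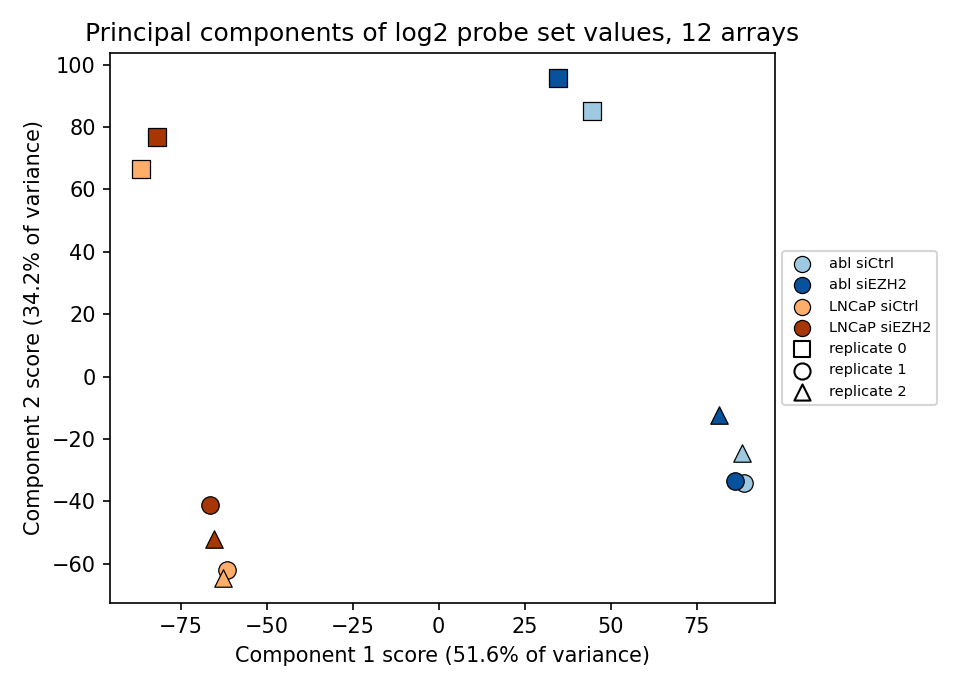
Scores of the 12 arrays on the first 2 principal components of the log2 values of 54613 probe sets; colour gives the group and the marker the replicate number. The horizontal axis (51.6% of the variance) parts abl from LNCaP, and the vertical axis (34.2%) parts replicate 0 of every group from replicates 1 and 2.

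In abl cells, transcripts fell far more often than they rose after EZH2 silencing. When siEZH2 and siCtrl arrays of the same replicate number were compared as pairs, 323 probe sets fell and 38 rose (limma, Benjamini-Hochberg adjusted p under 0.05), so that 89.5% of the changes were falls. After quantile normalization of the arrays 158 falls and 21 rises were left. The median size of a called change was 0.79 on the log2 scale, and 83 of the falls but 3 of the rises reached 2-fold. The probe sets named here had the smallest unadjusted p in the unpaired fit, where none passed (adjusted p = 1), and their adjusted p is that of the paired fit. Probe set 218308_at fell by 1.20 on the log2 scale (paired SE 0.111, n = 3 pairs, adjusted p = 0.00242), from 9.70 ± 0.191 to 8.49 ± 0.359 (SD), and was lower in each pair, by -1.41, -1.13 and -1.08. Probe set 213906_at, a dim one, fell by 0.81 (paired SE 0.121, adjusted p = 0.0126), from 5.53 ± 0.0549 to 4.71 ± 0.252 (SD). Among the rises, 225173_at gained 0.77 (paired SE 0.141, adjusted p = 0.0328), from 8.50 ± 0.322 to 9.28 ± 0.0978 (SD). Probe set 214536_at, also below the median level of all probe sets (mean 5.63 against 6.33), gained 0.61 (paired SE 0.102, adjusted p = 0.0209), from 5.11 ± 0.065 to 5.72 ± 0.138 (SD). The fit fixed before the data were examined, which ignores the replicate number, called 0 probe sets in abl, with 771 at an unadjusted p under 0.05, and its smallest adjusted p was 1. Left out in turn, pair 0 left 417 paired calls and pair 1 left 54, all falls. Leaving out pair 2 left 0, with 3928 at an unadjusted p under 0.05 in limma. All 361 kept their direction each time, which their selection from the same 3 pairs makes likely. The interquartile range was narrower in the siEZH2 array of each abl pair, by -0.01, -0.006 and -0.096.

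In LNCaP cells given dihydrotestosterone, both directions were better represented. The paired comparison found 362 probe sets lower and 177 higher after EZH2 silencing (limma, adjusted p under 0.05), or 67.2% falls, with a median called change of 0.67 on the log2 scale. The split depended on the scaling of the arrays: there were 213 falls and 182 rises after quantile normalization, and 652 falls and 167 rises when each array was centred on its median. Rises reached 2-fold in 24 probe sets and falls in 20. Probe sets were named as for abl, and none of them passed without the pairing (adjusted p = 1). Probe set 213295_at rose by 0.92 (paired SE 0.11, n = 3 pairs, adjusted p = 0.00916), from 6.33 ± 0.0482 to 7.25 ± 0.144 (SD). Probe set 225767_at rose by 0.92 (paired SE 0.125, adjusted p = 0.0128), from 8.41 ± 0.206 to 9.33 ± 0.153 (SD). Probe set 1555097_a_at, a dim one, fell by 1.01 (paired SE 0.121, adjusted p = 0.00916), from 5.22 ± 0.249 to 4.21 ± 0.112 (SD), and was lower in each pair, by -1.10, -1.26 and -0.66. Probe set 207663_x_at fell by 0.75 (paired SE 0.123, adjusted p = 0.023), from 10.86 ± 0.15 to 10.11 ± 0.103 (SD). Without the pairing, 0 probe sets passed in limma, with 1051 at an unadjusted p under 0.05, and 4 passed once LNCaP siCtrl replicate 0 was left out. Left out in turn, pair 0 left 1689 paired calls and pair 1 left 5, all rises. Leaving out pair 2 left 0, with 5079 at an unadjusted p under 0.05 in limma. All 539 kept their direction each time, which their selection from the same 3 pairs makes likely. The interquartile range was narrower in the siEZH2 array of each LNCaP pair, by -0.03, -0.119 and -0.081.

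The probe sets called in the 2 lines were mostly different ones. This alone does not show different responses, since in simulated data the paired fit recovered 32.8% of 1.5-fold changes in each line. Of 2-fold changes it recovered 70.1% in abl and 73.1% in LNCaP. The median called changes, 0.79 in abl and 0.67 in LNCaP on the log2 scale, lay between these 2 sizes, though selection can inflate them. Missed calls may therefore account for only part of the small overlap. Of the 323 falls in abl and 362 in LNCaP, 22 were shared, where independent lists of these sizes would share 2.14. Of the 38 and 177 rises, 6 were shared, against 0.123 for independent lists, and no probe set was called in opposite directions. The 2 comparisons have no array in common, but the array properties given above moved alike with the siRNA in both lines, and a common shift of that kind would also give shared calls. The largest shared changes, chosen after their values were seen, were those of 203358_s_at and 200821_at. Probe set 203358_s_at fell by 1.70 in abl (paired SE 0.212, adjusted p = 0.00608) and fell by 1.21 in LNCaP (paired SE 0.212, adjusted p = 0.0279). Probe set 200821_at rose by 1.10 in abl (paired SE 0.198, adjusted p = 0.031) and by 2.17 in LNCaP (paired SE 0.198, adjusted p = 0.00916). Neither passed without the pairing (adjusted p = 1). The fall of 203358_s_at in abl was the largest called there, and the rise of 200821_at in LNCaP the largest called there. Both kept their direction in all 3 pairs of both lines. In unpaired group means, the abl change of 200821_at was 0.63 without abl siCtrl replicate 0 and 0.71 without abl siEZH2 replicate 1. It was 1.62 without abl siEZH2 replicate 0 and 1.53 without abl siCtrl replicate 2. Leaving out a single array gives the 2 siRNAs unequal shares of replicate 0, so these values do not show dependence on that array. With all 4 replicate 0 arrays left out, the change was 1.15.

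The abl falls had a small median change in LNCaP, whereas the probe sets called in LNCaP had medians over the abl pairs that went the same way. The 323 probe sets that fell in abl, by a median of 0.81 on the log2 scale, had a median change of -0.027 in LNCaP, with quartiles of -0.19 and 0.077, and 80 of them were lower in all 3 LNCaP pairs. That median lay at the 1.22 percentile of 10000 random lists of the same size matched on mean level, 95% of which had medians between -0.023 and 0.024. The 362 probe sets that fell in LNCaP, by a median of 0.64, had a median change of -0.22 in abl, and 215 were lower in all 3 abl pairs. This was below all 10000 matched lists, of which 95% lay between -0.031 and 0.0087. The 177 that rose in LNCaP, by a median of 0.73, had a median change of 0.23 in abl, above all 10000 matched lists, and the 38 that rose in abl had one of 0.18 in LNCaP, also above all of them. The matched lists were drawn over probe sets with the arrays held fixed, so these percentiles measure no spread between arrays. A shift common to the pairs would also give extreme percentiles. Each set was chosen for its change in its own line, which can inflate its median there, so the smaller medians in the other line are no measure of a weaker effect. In the limma test of the difference between lines, 1 of the 323 and 0 of the 362, 177 and 38 passed, with 278, 229, 129 and 27 at an unadjusted p under 0.05. Over all 54613 probe sets, 4463 were at an unadjusted p under 0.05. The test reuses the change and the variance by which each set was chosen. Its small unadjusted p therefore follow in part from that choice and do not show effects particular to a line. When the sets were chosen from pairs 1 and 2 alone, which was done after seeing the data, the 361 abl falls had a median change of -0.79 in abl pair 0 and 0.28 in LNCaP pair 0. The 989 LNCaP falls chosen so had a median change of -0.26 in LNCaP pair 0 and -0.097 in abl pair 0, and the 700 LNCaP rises 0.13 and 0.014. The 56 abl rises had 0.16 in abl pair 0 and 0.31 in LNCaP pair 0. Over all probe sets, the 2 effects correlated with Pearson's r = 0.27 and Spearman's rho = 0.24. This is a correlation across probe sets, which are not independent replicates, and the common shift of the array properties would add to it. It was -0.032 between the replicate 0 pairs, 0.27 between the replicate 1 pairs and 0.24 between the replicate 2 pairs, and fell to 0.011 without abl siCtrl replicate 1 and to 0.016 without abl siEZH2 replicate 0. Without any other single array it lay between 0.14 and 0.38. These leave-out values use unpaired group means, and a left-out array gives the 2 siRNAs of its line unequal shares of replicate 0. That imbalance can itself move the correlation, so the values do not show that single arrays carry it.

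**Figure D2:**
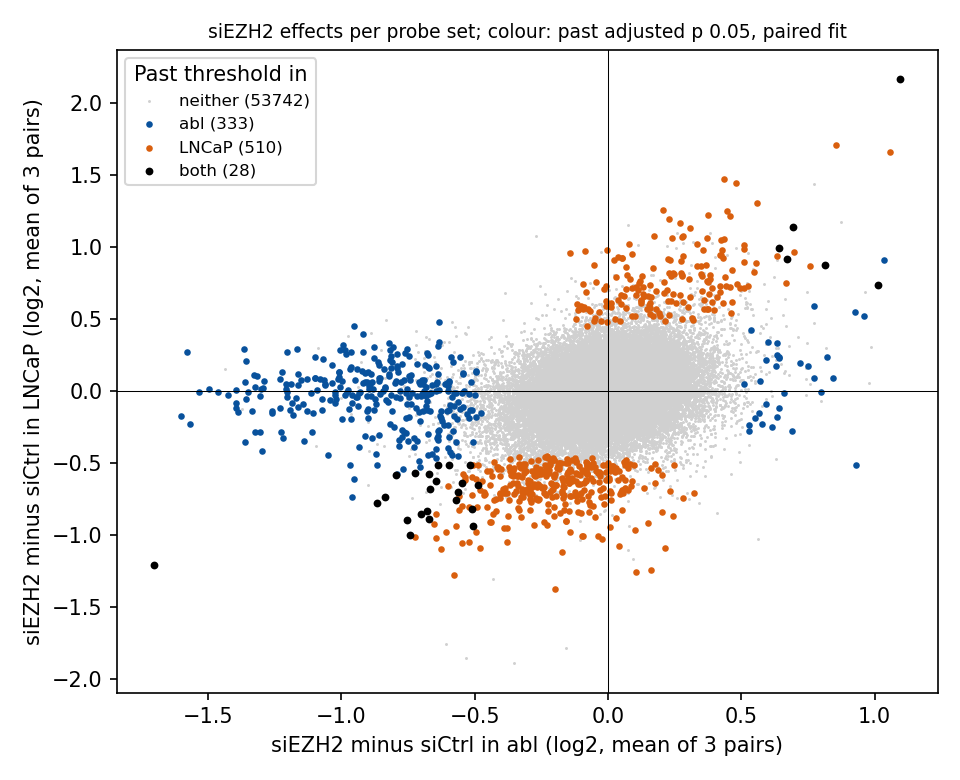
Change after EZH2 silencing of each probe set in abl (horizontal axis, log2) and in LNCaP (vertical axis, log2), each the mean of 3 pairs; colour marks probe sets past an adjusted p of 0.05 in the paired fit. The 323 abl falls spread to the left along a LNCaP change near 0 (median -0.027), and the 362 LNCaP falls lie below, shifted to the left (median abl change -0.22).

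Testing the difference between the lines directly gave few calls. The contrast of the abl effect minus the LNCaP effect covers cell line, routine growth medium and hormone together, since abl cells had vehicle and LNCaP cells dihydrotestosterone. In the paired fit, 1 probe set passed, 204318_s_at, which is named after its values were seen. It fell by 1.10 in abl (adjusted p = 0.00242) and stood at 0.23 in LNCaP (adjusted p = 0.311), a difference of -1.33 on the log2 scale (paired SE 0.141, n = 3 pairs per line, adjusted p = 0.0432). The next candidates did not pass in this fit. The difference was 1.02 for 203946_s_at (paired SE 0.154, adjusted p = 0.0538), 0.87 for 214536_at (paired SE 0.144, adjusted p = 0.0769), -1.05 for 213906_at (paired SE 0.171, adjusted p = 0.0723) and -1.16 for 1552682_a_at (paired SE 0.191, adjusted p = 0.0764). In LNCaP siCtrl arrays 213906_at and 1552682_a_at were dim, at 3.40 and 3.85. Without pairing 0 probe sets passed in limma, with 510 at an unadjusted p under 0.05, and the paired fit had 4463 at an unadjusted p under 0.05. Without pair 0 the paired fit called 54, and without pair 1 or pair 2 it called 0, with 3549 and 3365 at an unadjusted p under 0.05. After quantile normalization it called 0 too, with 4298 at an unadjusted p under 0.05. It called 105 with a variance trend and 23 without probe sets ending in _x_at or _s_at. With a batch term for replicate 0 in place of the pairs, chosen after seeing the data, 67 passed, among them all 5 probe sets named here, with unchanged differences and adjusted p between 0.0346 and 0.0458. With the 4 replicate 0 arrays left out of the unpaired fit, also chosen after seeing the data, 11 passed and none of these 5 (adjusted p between 0.0931 and 0.278).

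The control cells of the 2 lines differed in many transcripts. Without pairing, 10818 probe sets differed between abl siCtrl and LNCaP siCtrl arrays (limma, adjusted p under 0.05), 8885 higher and 1933 lower in abl, and with the replicate number as a block 24293 differed, 20219 higher and 4074 lower. Line, routine growth medium and hormone differ together here too, and the arrays of the lines may have been processed apart. The deposited values had a median difference of 0.24 on the log2 scale over all probe sets, higher in abl. After centring each array on its median, 3530 probe sets were higher and 4051 lower, and after quantile normalization 4567 were higher and 4923 lower. The largest differences, on the deposited scale, were far outside this shift. Probe set 236121_at was at 12.7 ± 0.281 in abl and 5.80 ± 0.922 in LNCaP (SD, n = 3), a difference of 6.94 (SE 0.481, adjusted p = 8.82e-06), and 232482_at was higher in abl by 6.57 (SE 0.26, adjusted p = 1.83e-07). Probe set 204540_at was at 6.54 ± 0.258 in abl and 13.3 ± 0.484 in LNCaP (SD, n = 3), a difference of -6.80 (SE 0.259, adjusted p = 1.38e-07). Probe set 213564_x_at differed by -6.11 (SE 0.603, adjusted p = 9.31e-05). Leaving out abl siCtrl replicate 2, LNCaP siCtrl replicate 1 or LNCaP siCtrl replicate 2 lowered the unpaired count to 6996, 6647 and 6783.

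**Figure D3:**
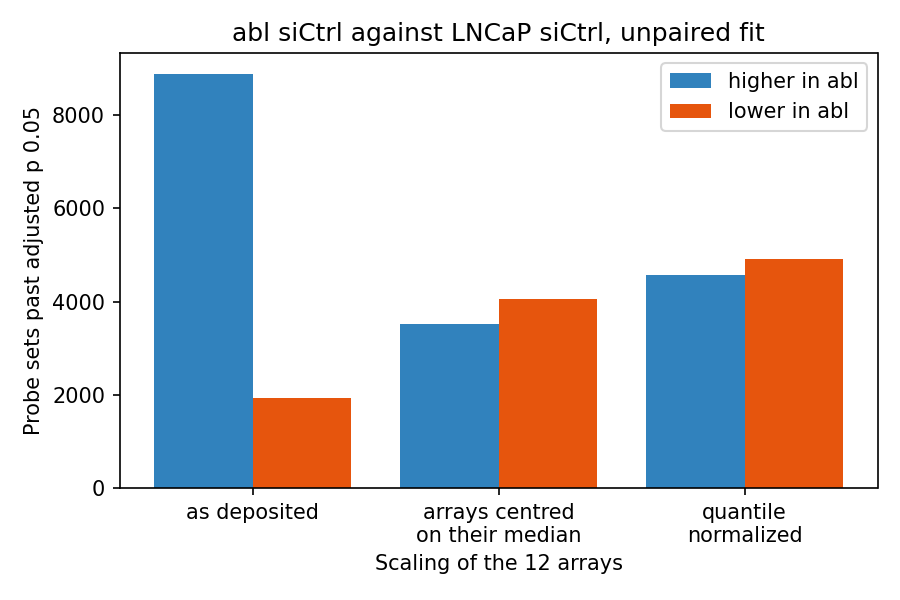
Number of probe sets past an adjusted p of 0.05 (vertical axis) that were higher or lower in abl siCtrl than in LNCaP siCtrl arrays, unpaired fit, under 3 scalings of the arrays (horizontal axis). As deposited, 8885 were higher and 1933 lower in abl; after median centring or quantile normalization the 2 directions are about equal in number.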

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

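Of the tests below, those without replicate 0 or with a batch term for it, of the 3' to 5' gap, of the share of falls under another scaling, of the signal range, of a quality shift common to both lines and of the control lines under another scaling were chosen only after the result was seen.

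The siEZH2 effect went opposite ways in the 2 lines in every pair in the 5 probe sets named for the difference between lines. They were picked for a well-supported difference, so their opposite signs follow in part from that choice. Over all probe sets tested, 1892 (3.46%) were opposite in every pair. In each of the 5 the change of 1 line did not pass in the paired limma fit. It was that of abl for 203946_s_at (adjusted p = 0.385) and that of LNCaP for the others (adjusted p between 0.278 and 0.392). Probe set 204318_s_at, with an abl minus LNCaP difference of -1.33 on the log2 scale, also passed the paired test of the difference (adjusted p = 0.0432). The difference was -1.16 for 1552682_a_at, 1.02 for 203946_s_at, -1.05 for 213906_at and 0.87 for 214536_at, and these did not pass in the paired fit (adjusted p between 0.0538 and 0.0769). In LNCaP siCtrl and siEZH2 arrays, 213906_at stood at 3.40 and 3.64 and 1552682_a_at at 3.85 and 4.18. These levels lie below the lower quartile of every LNCaP array (4.69 or more), where a fall could hardly be seen. With a batch term for replicate 0 in place of the pairs, chosen after seeing the data, all 5 passed (adjusted p between 0.0346 and 0.0458), and with the 4 replicate 0 arrays left out of the unpaired fit none did (adjusted p between 0.0931 and 0.278). The paired fit without them kept 204318_s_at alone of the 5 (adjusted p = 0.0378, the others between 0.0595 and 0.125). No group has enough arrays for a test of single outlying arrays.

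The 4 replicate 0 arrays stood apart from the other 8 in every group, and the contrast between them held 91.6% of the within-group variance, where 3 exchangeable replicates give 50%. Array scaling alone is argued against, since the share stayed at 91.2% after quantile normalization. A difference in RNA integrity or labelling remains open and would be consistent with the wider 3' to 5' gap of the HSAC07 control probe sets in replicate 0 (exact permutation p = 0.00202). The control probe set AFFX-HUMRGE/M10098_5_at stood at 12.4 ± 0.798 (SD, n = 4) in replicate 0 and 8.05 ± 0.698 (SD, n = 8) elsewhere (exact permutation p = 0.00202). All control probe sets with bio or cre in their identifier were also higher in replicate 0 in all 4 groups. Their mean differences ran from 0.41 (AFFX-r2-P1-cre-3_at) to 1.175 (AFFX-r2-Ec-bioB-3_at). What raised them was not tested, so the controls do not single out RNA integrity or labelling. No biological explanation was tested, since the design gives replicate 0 no separate meaning.

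In abl, 89.5% of the paired calls were falls. Array scaling and a narrower signal range in the siEZH2 arrays are argued against: after quantile normalization, which gives all arrays one distribution, 158 of 179 calls were falls (88.3%), and the 165 falls that ended kept their median size (-0.71 before, -0.70 after) with a larger median SE (0.126, then 0.138). The 7 array properties that moved alike in all 6 pairs shifted in LNCaP by 0.77 to 2.83 times their abl mean, while the abl falls had a median change of -0.027 in LNCaP. This argues against a common shift in these 7 properties as the whole explanation. They were picked for moving alike, so quality shifts that show in other properties are not covered. The HSAC07 gap of the abl pairs lay mostly in pair 0 (0.229, against 0.0129 and 0.0045), and falls were 86.6% of 417 calls without pair 0 and all 54 calls without pair 1, with 0 calls in limma without pair 2 (3928 at an unadjusted p under 0.05), so that gap may add to the falls but leaves those without pair 0 unexplained. Other control probe sets had a larger mean rise in abl, such as AFFX-HUMRGE/M10098_5_at by 0.954 ± 0.755 against 0.505 ± 0.687 in LNCaP (SD, n = 3 pairs). In a paired limma fit of the 62 control probe sets, 0 passed in abl and 0 for the difference between lines. For AFFX-HUMRGE/M10098_5_at the difference was 0.449 (SE 0.469, adjusted p = 0.948). A quality difference particular to abl remains open, as do the silencing of EZH2 and off-target effects, which were not tested.

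Of the calls between the control lines, 82.1% were higher in abl as deposited and 46.6% after centring each array on its median.

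Regrouping the arrays adds little in designs of this size. With 10 splits of 6 arrays, no share under 0.05 can be had. The unpaired counts were 0 in abl with a highest other split of 0 (10 of 10 as large), 0 in LNCaP with a highest other of 0 (10 of 10), and 10818 for the control lines with a highest other of 0 (1 of 10). Swapping arrays within pairs gives 4 splits, again too few. The paired counts were 361 in abl, 539 in LNCaP and 24293 for the control lines, each with a highest other of 0 (1 of 4). For the difference between lines, the unpaired count was 0, so all 100 splits drawn were as large and nothing follows on chance. The highest had 21510 and the only other above 0 had 14418, which points to a structure of the arrays other than the siRNA. Both placed the abl replicate 0 arrays in one arm and the LNCaP replicate 0 arrays in the other, but so did 5 splits with 0 calls, so this arrangement alone does not set them apart. In the paired fit, 4 of 32 splits gave at least the 1 call, the real one included. The other 3, with 245, 1240 and 122 calls, all turned LNCaP against abl in 2 or 3 pairs and so count mostly the sum of the 2 effects, and nothing follows from them on chance.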

How the results depend on the processing

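Leaving out the replicate 0 arrays, the batch term and all alternatives on top of the pairing were chosen only after the result was seen. No value is given for the fold change of EZH2 or for the gene lists, because no annotation of the probe sets was used. The alternatives that need gene names (the gene-level tables, the mean over probe sets of a gene, list tests with an estimated correlation) were not run. All named probe sets kept their direction under every alternative that tested them, which their choice for small p or large changes in the same arrays makes likely. The unpaired count of 0 in abl became 361 with the replicate block, 322 without the replicate 0 arrays and 483 with a batch term for replicate 0. In LNCaP it became 539, 1027 and 903, and for the difference between lines 1, 11 and 67. For the control lines 10818 became 24293, 26855 and 27054, and 4376 among probe sets above the median level. Leaving out single arrays gave 0 calls in abl and for the difference each time, 0 to 4 in LNCaP and 6647 to 11876 for the control lines, and a correlation of the 2 effects of 0.011 to 0.38. These fits are unpaired, and the unequal shares of replicate 0 that a left-out array creates can themselves move the correlation. The paired abl count of 361 became 179 with quantile normalization, 672 with a variance trend and 189 without _x_at and _s_at probe sets, and all 179 were among the 361. The paired LNCaP count of 539 became 819 with median centring, 898 above the median level, 1210 with a trend, 332 without _x_at and _s_at probe sets and 200 from the 6 LNCaP arrays alone. The paired call of 1 for the difference became 0 with quantile normalization, 105 with a trend and 23 without _x_at and _s_at probe sets. The paired control-line count of 24293 became 12455 above the median level, where fewer probe sets are tested. Leaving out 1 replicate number at a time gave paired counts of 0 to 417 in abl, 0 to 1689 in LNCaP, 0 to 54 for the difference and 13189 to 29195 for the control lines. The 2 pairs left then give 2 residual degrees of freedom, or 1 for the control lines, and counts without replicate 0 were the highest. Apart from the smaller fits and filters, the cause was not tested. The remaining 66 unpaired and 12 paired counts stayed within 1.5 times. Unpaired counts of 0 that stayed at 0 are among them and show no stability. A similar count can also hold other probe sets: with quantile normalization the paired control-line fit called 16942, of which 12476 were among the 24293. Of the values of single probe sets under alternatives, 42 passed the threshold where the unpaired fit had not. The signal over background of the probe sets was not given, so how far dimness limits the calls is unknown.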

Other observations

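The test here was chosen only after the result was seen. The small median change of the abl falls in LNCaP might be a matter of probe sets too dim in LNCaP to fall further. The falls were not absent there: of the 323, 22 were also called as falls in LNCaP, where independent lists would share 2.14. In all 3 LNCaP pairs 80 were lower and 37 higher, and 1 passed the paired limma test of the difference between lines. The 323 probe sets stood at a median of 8.65 in abl siCtrl arrays and 6.83 in LNCaP siCtrl arrays, where the median of all probe sets was 6.19. The 213 of them above that LNCaP median had fallen by a median of 0.78 in abl and changed by a median of -0.062 in LNCaP, with 95% of resampled medians between -0.11 and -0.017. The resampling was over probe sets, so it measures no spread between arrays. The LNCaP median is 0.079 of their abl change, which their selection may inflate. It argues against dimness for these 213 as the whole explanation, while the other 110 stay open. The hormone, the routine growth medium, the cell line and a weaker silencing in LNCaP are open explanations that the design does not separate.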
